A study of Drosophila melanogaster with 4 samples.

How the data were processed

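Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on nuclei of Drosophila melanogaster larvae of the third instar, from the wild-type strain Oregon-R. The antibody was directed against LSD1. Per the labels, chromatin was fixed with formaldehyde and sheared by sonication before immunoprecipitation. The series comprised 4 samples, 2 LSD1 ChIP libraries and 2 input libraries of unselected chromatin. The labels give each replicate number and say which input served which ChIP library. They do not say whether the replicates came from separate collections of larvae, so the spread between them may be technical.

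The deposited data are 3 lists of regions of significant enrichment, called clusters here: one list for each ChIP replicate and one for the whole replicate set, called the combined list. Per the submitters' processing notes, Bowtie 0.12.7 was among the tools used. The caller, its threshold, the scaling of ChIP against input and the way the replicates were combined are not given in the sources used here. Coordinates are those of FlyBase release 5, per the file headers, and are given 1-based. Each cluster carries one value from the authors, and no deposited header line names its unit. It was read as a log2 ratio of the deposited ChIP and input signals, which rests on the values that occur at least 4 times in a list. Of these, 26 of 45 in replicate 1, 56 of 133 in replicate 2 and 30 of 122 in the combined list lay at log2 of a ratio with a denominator up to 60 from the commonest value, within 1e-06 of the ratio. With the natural log 0 did in each list, and with the log to base 10 0, 1 and 0. This check was chosen after the lists were seen, and the unit of all other values is assumed. The value belongs to the authors and was used to describe, rank, filter and test clusters within a list. Across lists it entered only the correlation of paired clusters, which does not depend on the scaling of either list, and the gap between X and the autosome arms at the low end of each list. Levels were not compared between lists. Wider clusters had larger values (Spearman's rho of 0.74 in replicate 1, 0.63 in replicate 2 and 0.50 in the combined list, across clusters). The input libraries entered only through the authors' own calls. The lists give no read numbers, so the sequencing depth is unknown, and a region without a cluster cannot be told from one with too few reads. One entry of the combined list is marked as depleted, on 2R from 3273876 to 3275686 with a log2 value of -0.03, and was left out.

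From these lists, clusters of the replicates were compared by overlap of at least 1 bp. The overlap expected by chance was taken from 1000 circular shifts of one list along each sequence, with the lengths in the file headers, and the one-sided p has 0.001 as its smallest value. Values of shared and single clusters were compared by a two-sided rank permutation test with 100000 permutations, whose smallest p is 1e-05. Paired clusters, each the other's largest overlap, were correlated across clusters with the same number of permutations. Clusters are not independent replicates, and these p-values describe the 2 libraries at hand. Shares carry exact 95% binomial intervals and densities exact 95% Poisson intervals, both covering counting error only. The numbers of clusters on 2L, 2R, 3L, 3R, X, chromosome 4 and all other sequences were compared between replicates by chi-square with 100000 permutations of the list labels. Values on X, chromosome 4 and the heterochromatic (Het) scaffolds were compared with those on the 4 autosome arms by permutation, as 6 tests with Benjamini-Hochberg adjustment. Sharing on the same sequences was also compared by Fisher's exact test, but that test has no expectation for the unequal coverage of the replicates on each sequence, so nothing rests on it. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

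The overlap search and its shifts were tested on simulated data. In 40 simulations of replicate 2 placed at random against the 5704 clusters of replicate 1, 7.5% had p under 0.05. Random placement removes the clumping of the real list, so this does not show how the shifts behave on such a list. The 1711 planted clusters were exact copies of clusters of replicate 1. That 100% of them were counted as shared checks the code of the search and says nothing on its sensitivity. The comparisons, the alternatives and the rule for named clusters were fixed before the data were examined. The 1 Mb windows, the centromere-proximal megabases, clusters over 10 kb, the comparison of values within 10 equal classes of width (10000 permutations), and the values and sharing by chromosome were chosen after the lists were seen. Named clusters are the 15 with the largest value and the 5 widest of the combined list that overlap a cluster of each replicate, and the 3 with the largest value among the single clusters of each replicate. Alternatives covered the overlap rule, stricter values, the chromosomes included, random placement, merging of neighbours and each replicate alone.

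Placement relative to promoters and gene features and the 19 gene lists fixed beforehand were not analysed here. The only gene table at hand is of release 6, and coordinates were not converted between releases, so clusters are named by position. Also for this reason Su(var)3-3 (the gene of LSD1), CoRest and Rpd3, which were to be named whatever their values, have no value here.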

Results

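LSD1, the product of Su(var)3-3 in the fly, is a histone lysine demethylase known for its part in gene silencing and in the formation of heterochromatin. Its chromatin sites were mapped by ChIP-seq in nuclei of Oregon-R larvae of the third instar, with 2 ChIP replicates, each called against its own input. Replicate 1 held 5704 clusters of enrichment over 28.5 Mb and replicate 2 held 7936 clusters over 30.7 Mb. The combined list of the replicate set held 9853 clusters over 41.4 Mb. Of the 5 large chromosome arms, clusters covered 23.5% in replicate 1, 25.3% in replicate 2 and 34.1% in the combined list. Read depth is unknown for all of them. The design implies 3 questions: how far the replicates mark the same regions, how the combined list relates to them, and how the enrichment is spread over the chromosomes.

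The enrichment took the form of many short clusters and a smaller number of broad domains. The median width was 2434.5 bp in replicate 1 and 2121 bp in replicate 2, a mean of 2278 ± 222 bp (SD, n = 2). Clusters wider than 10 kb made up 11.6% of the clusters of replicate 1 and 7.0% of those of replicate 2, but 45.6% and 33.1% of the covered bases. All 659 such domains of replicate 1 overlapped a cluster of replicate 2, and all 553 of replicate 2 overlapped one of replicate 1. When the other list was shifted, 64.8% and 57.7% of these domains did so on average, and at most 74.1% and 67.1% (permutation p = 0.001 for each). Among clusters of 10 kb or less, 78.4% and 63.8% overlapped, against 37.8% and 32.7% when shifted (permutation p = 0.001 for each). The median gap between neighbours was 4882 bp in replicate 1 and 3157 bp in replicate 2.

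The widest domain found in both replicates lay on 3L from 707156 to 826406. It spanned 119251 bp, and clusters of replicate 1 covered 96.7% and those of replicate 2 96.9% of it, in 2 and 4 pieces. A domain of 105201 bp on 3R from 5695712 to 5800912 was covered to 99.3% and 97.0%, in 2 pieces in replicate 1 and 7 in replicate 2. On 3L from 10309858 to 10409082, a domain of 99225 bp was covered to 95.1% and 96.7%, in 4 and 5 pieces. The domain on 2L from 14472378 to 14568790, of 96413 bp, was covered to 91.1% and 97.2%, in 7 pieces in replicate 1 and 4 in replicate 2. The domain on 2L from 12457440 to 12548168 was a single cluster in replicate 1 and 2 clusters in replicate 2, and its value of 1.34 in the combined list was the highest of these 5.

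The replicates marked largely the same regions. Of the clusters of replicate 1, 4613 (80.9%, 95% interval 79.8 to 81.9) overlapped one of replicate 2, against a mean of 40.9% and a maximum of 48.3% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest the shifts can give). Of the clusters of replicate 2, 5265 (66.3%, interval 65.3 to 67.4) overlapped one of replicate 1, against 34.5% and at most 40.4% when shifted (permutation p = 0.001). In bases, 23.3 Mb lay in both lists, which is 65.0% of the 35.9 Mb in either, against 14.0% when shifted (permutation p = 0.001). With a reciprocal overlap of at least 50%, 59.6% and 42.9% of the clusters were shared, against 8.16% and 5.88% when shifted.

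Clusters seen in both replicates were wider than those seen in one, and without regard to width they also had larger values. In replicate 1 the median value was 0.68 for shared clusters and 0.52 for the 1091 single ones, a difference of 0.17 on the log2 scale. In replicate 2 the medians were 0.65 and 0.58 for the 2671 single ones, a difference of 0.07. Both differences had a two-sided permutation p of 1e-05, the smallest the permutations can give. Shared clusters had median widths of 3069 and 2810 bp, single ones of 1684 and 1628 bp. A wider cluster is more often overlapped by chance and wider clusters had larger values, so the overlap rule itself sets part of these differences. Within 10 equal classes of width, the mean difference between the medians of shared and single clusters was 0.05 in replicate 1, higher in 7 of the 7 classes with at least 20 clusters of each kind. In replicate 2 it turned to -0.03, higher in 3 of 9 classes. The test was made on the ranks of the values within all 10 classes and not on these means. By rank, shared clusters were higher in replicate 1 and lower in replicate 2 (two-sided permutation p = 0.0001 for each, the smallest that 10000 permutations can give). Across the 4211 paired clusters the values of the replicates were correlated, with Pearson's r of 0.74 and Spearman's rho of 0.69 (permutation p = 1e-05 for each, across clusters). The widths of the same pairs were correlated too, with r of 0.90 and rho of 0.75. As values go with width within each list, part of the correlation of values may go with width.

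**Figure D1:**
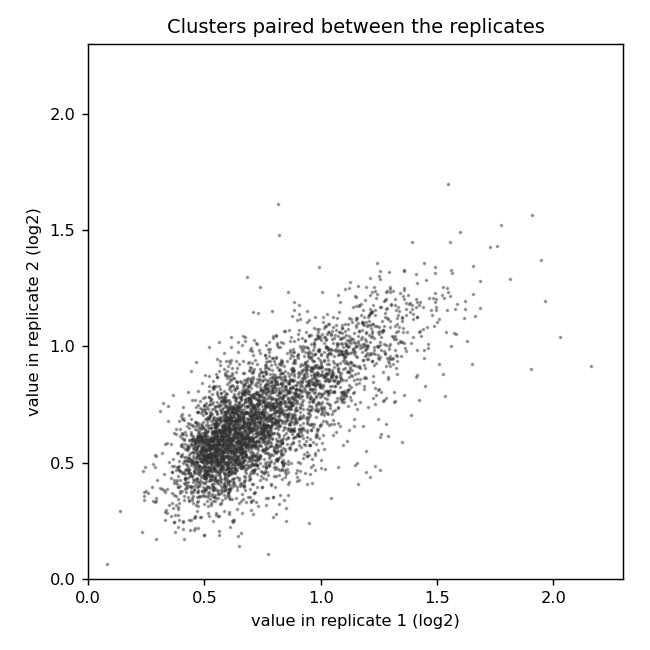
Value of each of the 4211 paired clusters in replicate 1 (horizontal, log2) against its partner in replicate 2 (vertical, log2), each point a pair. The values rise together, with Spearman's rho of 0.69, and the widths of the pairs do so as well, with rho of 0.75. The scaling of each list is not given, so the axes show order within a list and not a difference in level between lists.

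Among the clusters of the combined list found in both replicates, 11 of the 15 with the largest values lay on the 5 large arms. The highest, 1.74, was on 2R from 1300060 to 1306570, with values of 1.91 in replicate 1 and 1.56 in replicate 2. A second site on 2R, from 1145604 to 1149352, had 1.63 in the combined list, 1.95 in replicate 1 and 1.37 in replicate 2. A further one on 2R, from 557132 to 560620, had 1.43. It lay in the megabase of 2R nearest the centromere, where clusters covered 6.66% in replicate 1 and 5.95% in replicate 2. On 2L a domain of 25215 bp from 158114 to 183328 had 1.65, one of 19533 bp from 6074178 to 6093710 had 1.59, and one of 12745 bp from 8711448 to 8724192 had 1.40. On 3L a domain from 9363840 to 9381040 had 1.55 and one from 16028342 to 16045378 had 1.51. On 3R a site of 5399 bp from 17120728 to 17126126 had 1.53 and a domain of 17063 bp from 877718 to 894780 had 1.44. The X chromosome contributed a domain of 21173 bp from 5776624 to 5797796, with 1.48. The other 4 lay on unplaced or heterochromatic sequence, where 52 of the 3758 combined clusters found in both replicates lay. These were on U from 3441732 to 3445870 and from 1102288 to 1104500 (1.59 and 1.53), on 2LHet from 29980 to 33802 (1.58) and on 3LHet from 458206 to 461080 (1.41). The number of input reads behind a value is unknown on the arms as on these sequences, so large values from few input reads are not excluded on either.

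Some of the largest values belonged to clusters found in one replicate only. The 3 largest of these in replicate 1 were on 3L from 23665997 to 23668462 (3.08), on 3RHet from 439356 to 440790 (2.98) and on 2LHet from 348478 to 349871 (2.33). In replicate 2 the 3 largest were on 2R from 1278066 to 1280367 (1.87) and on X from 21592547 to 21594292 (1.86) and from 11210155 to 11212174 (1.64). None of these overlapped a cluster of the other replicate, and those on 2LHet and on X from 21592547 were also outside the combined list. They were short, from 1394 to 2466 bp wide. The one on 3RHet lies within the cluster with the largest value of the combined list (3.57). No list says how many input reads lie behind a value, so large values from windows with almost no input reads are not excluded for these clusters.

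The combined list took in nearly all of both lists and added clusters of its own. It overlapped 5653 of the clusters of replicate 1 (99.1%, interval 98.8 to 99.3) and 7714 of those of replicate 2 (97.2%, interval 96.8 to 97.6). Of its 9853 clusters, 3758 (38.1%, interval 37.2 to 39.1) overlapped clusters of both replicates. These 3758 clusters, each counted in full, held 75.0% of its covered bases (31.1 Mb), while 23.3 Mb lay in both replicate lists. A further 991 (10.1%) overlapped replicate 1 only, 2238 (22.7%) replicate 2 only, and 2866 (29.1%, interval 28.2 to 30.0) neither. The clusters found in both had a median width of 4940 bp and a median value of 0.58. Those found in neither had 1219 bp and 0.39, and 61.2% of them were narrower than 1301 bp, the narrowest cluster of either replicate. The combined list is not independent of the replicates, so no test was made. At equal numbers of top clusters per list, 55.3% of the combined ones were found in both, and with reciprocal overlap 25.1%.

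**Figure D2:**
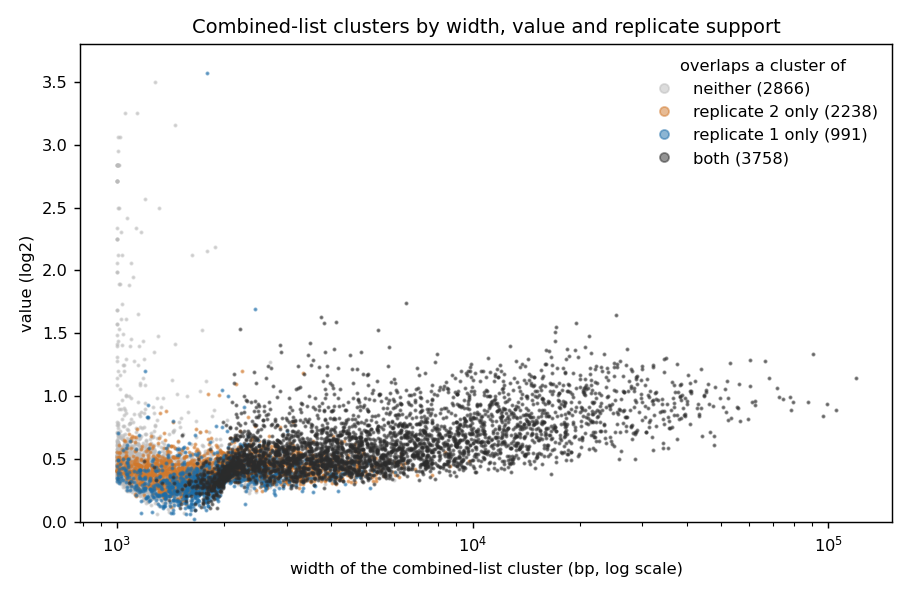
Width (horizontal, bp, log scale) and value (vertical, log2) of each cluster of the combined list, coloured by whether it overlaps a cluster of both replicates, of replicate 1 only, of replicate 2 only or of neither. Clusters found in both extend to 119251 bp and reach values up to 1.74, and the 40 largest values, all of 2.06 or more, belong to clusters at most 1887 bp wide.

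The 4 autosome arms lay within 4 percentage points of one another in cluster coverage, and X lay below them. In replicate 1 clusters covered 22.9% of 2L, 24.5% of 2R, 26.6% of 3L and 22.8% of 3R, and in replicate 2 they covered 26.1%, 26.5%, 29.0% and 25.4%. The X chromosome had 20.9% and 19.2%. Per Mb, X held 44.1 clusters (interval 41.4 to 46.9) in replicate 1 and 55.3 (interval 52.2 to 58.4) in replicate 2. The 4 autosome arms together held 47.2 (interval 45.9 to 48.6) and 67.2 (interval 65.6 to 68.9). The relative density of X was thus 0.88 ± 0.08 (SD, n = 2), by counting error clearly lower in replicate 2 only. In replicate 1 arm 3R held fewer clusters per Mb than X, 43.9. The clusters on X had the higher values, with medians of 0.71 against 0.62 in replicate 1 and 0.66 against 0.60 in replicate 2 (two-sided permutation, adjusted p = 1e-05 in each). The 5th percentile of the values on X also lay above that of the autosome arms, by 0.060 in replicate 1 and 0.045 in replicate 2. No read numbers are at hand, so a higher lowest callable value on X cannot be told from stronger enrichment there. Among the top 50% of each list by value the direction of the density turned, and X held 1.17 ± 0.12 (SD, n = 2) times the density of the autosome arms. This turn goes with the higher values on X and carries the same limit.

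Chromosome 4, the small chromosome rich in heterochromatin, had the highest cluster density of the chromosomes, by counting error clearly so in replicate 2 only. Its density was 58.4 per Mb (interval 46.3 to 72.8) in replicate 1 and 93.9 (interval 78.3 to 111.8) in replicate 2, which is 1.32 ± 0.11 (SD, n = 2) times that of the autosome arms. Its clusters had median values of 0.81 and 0.78, higher by 0.19 and 0.18 than on the autosome arms (permutation, adjusted p = 1e-05 in each). As on X, a higher lowest callable value or few input reads cannot be told from stronger enrichment without read numbers. In covered bases the direction depended on the library: 20.2% of chromosome 4 was covered in replicate 1 and 27.4% in replicate 2, which is 0.83 and 1.03 times the share of the autosome arms together. Domains over 10 kb numbered 3.70 per Mb in replicate 1 and 2.22 in replicate 2. Their intervals reach up to 8.63 and 6.49 and so include the densities of the autosome arms, 5.60 and 4.98.

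The Het scaffolds, which hold assembled pericentric heterochromatin, together carried few clusters, with larger median values than the autosome arms. Clusters covered 1.81% of them in replicate 1 and 1.73% in replicate 2, with 63 and 65 clusters. Their median values were 0.97 and 0.94, higher by 0.35 and 0.34 than on the autosome arms (permutation, adjusted p = 1e-05 in each), and none was wider than 10 kb. XHet, of 0.204 Mb, departed from this in cluster density and, in replicate 1, in median value. It held 24.5 clusters per Mb (interval 7.95 to 57.2) in replicate 1 and 44.1 (interval 20.2 to 83.7) in replicate 2, from 5 and 9 clusters, and these intervals include the densities of the autosome arms. Its covered share, 4.56% in replicate 1 and 8.43% in replicate 2, was still below the 24.2% and 26.7% of the autosome arms together. Its median value in replicate 1 was 0.59, below the 0.62 of the autosome arms, and in replicate 2 it was 0.88. The unplaced sequence U held 10 and 13 clusters over 10.0 Mb. YHet and Uextra, both listed in the file headers, held none in any of the 3 lists. No list says which bases of these sequences could be called or how many input reads lie behind a value, so large values from windows with almost no input reads are not excluded here.

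**Figure D3:**
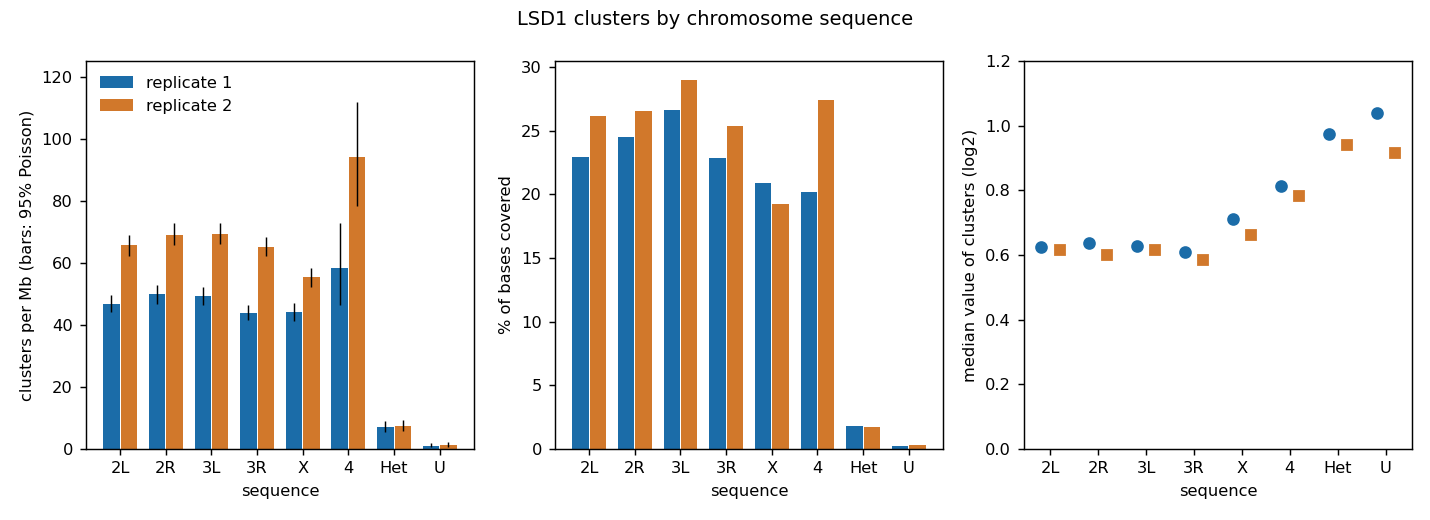
Clusters per Mb with 95% Poisson intervals (left), percent of bases covered (middle) and median value of the clusters in log2 (right), for each replicate on the large arms, chromosome 4, the Het scaffolds together and the unplaced sequence U. Density is highest on chromosome 4, coverage is lowest on the Het scaffolds and U, and median values are 0.97 and 0.94 on the Het scaffolds against 0.62 and 0.60 on the autosome arms together.

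Along the arms the same regions were rich or poor in both replicates. Over the 117 full windows of 1 Mb on the 5 arms, the covered share correlated between replicates with Pearson's r of 0.95 and Spearman's rho of 0.93 (permutation p = 1e-05 for each, across windows, which are not independent). The richest window was the first megabase of 3L, with 49.1% covered in each replicate, which holds the widest domain. Next came the first megabase of 3R (42.0 ± 6.6%, SD, n = 2), 2R from 2 to 3 Mb (41.4 ± 1.8%), 3L from 11 to 12 Mb (40.8 ± 2.9%) and 2L from 14 to 15 Mb (39.6 ± 5.7%). The adjacent window of 2L, from 15 to 16 Mb, was among the poorest, with 6.37 ± 1.79%, as was 2L from 17 to 18 Mb with 9.36 ± 1.47%. The megabase of the arm sequence nearest the centromere was poor on 3L (2.47 ± 0.07%), 2R (6.31 ± 0.50%), 2L (7.81 ± 0.27%) and X (10.0 ± 3.1%). That of 3R was the second richest of the 117 windows by the mean of the replicates and in replicate 2 (46.7%). In replicate 1 (37.4%) it ranked lower, below for example 2R from 2 to 3 Mb (40.1%). The Het scaffolds are not part of these megabases, and 3RHet was covered to only 1.04% and 1.09%. The lists do not say how near the centromere each arm sequence ends, so the arms may not be comparable here. They also do not say which bases could be called, so a poor megabase cannot be told from one with few callable bases.

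**Figure D4:**
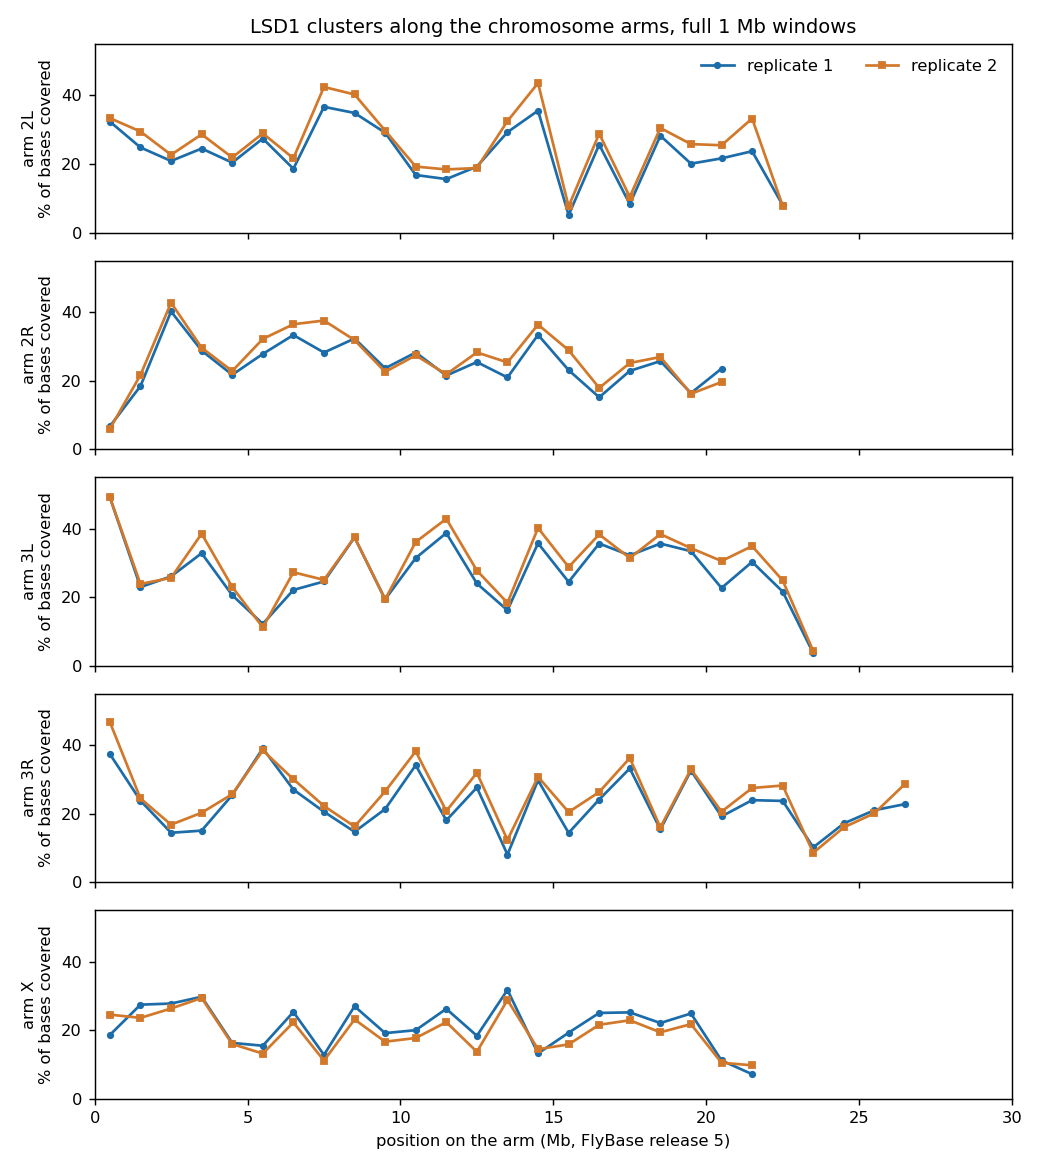
Percent of bases covered by clusters (vertical) in each full 1 Mb window along arms 2L, 2R, 3L, 3R and X (horizontal, Mb), for replicate 1 and replicate 2. Both lines peak at 49.1% in the first megabase of 3L, and replicate 2 lies above replicate 1 in 78 of the 95 autosome windows but in 3 of the 22 X windows.

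The replicates differed in how their clusters were divided between chromosomes. Replicate 2 held 1.42 times as many clusters as replicate 1 on the 4 autosome arms, 1.25 times on X and 1.61 times on chromosome 4 (chi-square of 12.8 over 7 sequence classes, permutation p = 0.046). The permutation of list labels takes no account of clusters that overlap between the lists, so this p is only a rough guide. Covered bases were 1.11 times as many on the autosome arms, 1.36 times on chromosome 4 and 0.92 times on X. The Het scaffolds together were also covered slightly less in replicate 2, 1.73% against 1.81%, with 65 clusters against 63. Per window, the median log2 ratio of replicate 2 to replicate 1 was 0.15 on the autosomes and -0.19 on X (two-sided permutation p = 1e-05, across windows, which are not independent). The shares of shared clusters go with this imbalance and are not counted as a further difference. On X, 73.7% of the clusters of replicate 1 and 74.6% of those of replicate 2 were shared, against 82.6% and 64.9% on the autosome arms.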

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

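The lists hold no read numbers, so no alternative could show what depth limits. Of 48 alternative values, 36 were counted as stable. Apart from those for the named clusters, these kept their direction and their side of the threshold or moved by less than the spread. This tally overstates stability. Values from each replicate alone lie within the SD of 2 replicates by construction, and the share of covered bases was counted for each replicate. Overlap of the replicates was judged by its p alone, so a fall from 80.9% to 59.6% and from 66.3% to 42.9% with reciprocal overlap was counted as stable. The named clusters had neither a threshold nor a spread, and 16 of 20 was counted as stable. The overlap of the replicates stayed above the shifted lists at a permutation p of 0.001 under each overlap rule, stricter list, set of chromosomes and way of placement tried, with shares from 42.9% to 81.0%. The difference between shared and single clusters and the correlation of paired clusters kept their sign at a permutation p of 1e-05 under reciprocal overlap and on the 5 arms alone. Width in place of value, 3 further values, decides nothing here and was set aside, because wider clusters are overlapped more often by the overlap rule itself. Compared within 10 classes of width, an alternative chosen after seeing the data, the difference was 0.050 in replicate 1 and reversed to -0.025 in replicate 2, so in replicate 2 the larger values of shared clusters go with their width. Of the combined clusters, 25.1% were in both replicates with reciprocal overlap and 55.3% at equal numbers of top clusters, against 38.1%. The density of X relative to the autosome arms, 0.88, was 0.79 in covered bases and reversed to 1.17 in the top 50% of each list by value. That of chromosome 4, 1.32, was 2.42 in that top 50% and 1.46 in the combined list, and reversed to 0.93 in covered bases, where replicate 1 alone gave 0.83 and replicate 2 alone 1.03, so that replicate 1 sets this reversal. The cause of these changes was not tested. Each replicate alone gave 0.82 to 0.93 for X and 1.24 to 1.40 for chromosome 4, median widths of 2121 to 2434.5 bp and median gaps of 3157 to 4882 bp. Merging neighbours under 1000 bp apart raised the mean of the median widths from 2278 to 2757 bp and that of the gaps from 4020 to 6994 bp, and the top 50% of each list by value had 4105 and 10684 bp. These shifts follow from the joining or removal of clusters. Of the 20 named combined clusters, 16 stayed in both replicates with reciprocal overlap. No paired analysis was possible because the input libraries come without lists of their own and each comparison is between 2 lists. The 3 results that need a release 5 annotation (promoters, gene features, gene lists) and their alternatives were not run.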

Other observations

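The test on the steps between the largest values was chosen after the result was seen; the other 3 were set down before their results.

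The largest values of the combined list stood apart from the rest. The 40 largest, all of 2.06 or more, lay in clusters with a median width of 1007 bp, 39 of them overlapped no cluster of either replicate, and 21 lay on the Het scaffolds or U. The top 3 were on 3RHet from 439086 to 440880 (3.57), on U from 6617168 to 6618448 (3.50) and on 3L from 12869332 to 12870382 (3.25). All 40 fell, within 1e-06, on log2 of a multiple of a sixth plus 1 constant, and none of the 40 largest values among clusters found in both replicates did. A candidate explanation is that these are ratios over windows with almost no input reads, where a few ChIP reads give a large value. No read numbers are at hand to show this directly. No biological explanation was tested, and ranking the combined list by value without asking for a replicate would put these sites first.

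A smaller minimum width in the combined list (1001 bp against 1301 bp in each replicate) may account for part of the 2866 clusters that neither replicate held. Among combined clusters at least 1301 bp wide, 14.6% (95% interval 13.8 to 15.4) were still in neither, against 29.1% of all. This lies between the bounds set beforehand, under 5% if width were the whole cause and over 15% if not, so the 1753 narrower clusters stay open while width leaves the other 1113 unaccounted for. How the replicates were combined is not given in the sources used here, and a gain from pooled reads was not tested.

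Replicate 2 had more and narrower clusters than replicate 1, and it covered less of X. Splitting of domains is one candidate explanation for the first: 963 clusters of replicate 1 had 2 or more partners in replicate 2, against 522 the other way. Yet merging neighbours under 1000 bp apart lowered the ratio of cluster numbers only from 1.39 to 1.29, which argues against splitting over such gaps as the whole cause, and 70.8% of the 2232 extra clusters came from single clusters. For X, fewer reads there in replicate 2, for example from another share of male larvae, should raise the lowest values called there. The 5th percentile of X values over that of the autosome arms differed between replicates by -0.015 (95% bootstrap interval -0.041 to 0.014), so this stays open because the interval includes 0 and no read numbers are at hand.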
